A study of Caenorhabditis elegans with 12 samples.

How the data were processed

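The series holds 12 RNA-seq libraries of Caenorhabditis elegans Bristol N2, the standard wild-type strain. Total RNA of worms at 6 numbered stages of development was depleted of ribosomal RNA. Per the labels' protocols, one aliquot of each stage was digested with RNase R, an exonuclease that degrades linear RNA and spares circular RNA, and the other was only kept at room temperature (mock). There were 6 mock and 6 RNase R libraries, 1 of each per stage. The labels describe stage 1 as embryo, stages 2 to 5 all as L1-L4 larvae and stage 6 as young adult, and nothing says that any condition was repeated in a separate culture.

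The values analysed came from 2 tables of A-to-G positions deposited for the whole series, 1 for C. elegans and 1 for human. An A-to-G position is an adenosine of the genome that reads as guanosine in RNA; ADAR enzymes, which convert adenosine to inosine in double-stranded RNA, leave this mark. Neither table has a header or a column that names a sample, so the libraries behind each site are unknown. The comparison of RNase R with mock, the comparison of stages and any test over replicates could therefore not be made from these tables, and no mean, SD or n over samples is given. The sequencing depth, the coverage of each position and the share of edited reads are unknown, so no editing level was calculated. The caller, its filters and the genome builds are not given in the sources used here.

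The C. elegans table gives, for each position, the chromosome, a 1-base interval, the 3 genome bases centred on the position, a whole number and a strand. The authors deposited the whole number in the score column of a BED layout without saying what it counts; it is called the score here and was not treated as a read count. The human table gives intervals alone. Neither the RNA behind it nor its donors or cells are described in the sources used here, so only sums over many positions on the 22 autosomes are reported for it, and no single position.

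Coordinates are those of the deposited tables, written 1-based. The C. elegans build was compared with the WBcel235 annotation through bases that an annotation fixes (start codons, and GT and AG at intron ends). With no shift, 30 of 124 such bases in the listed triplets matched. In the last sixth of chromosome III, 6 of 23 matched with no shift, and among shifts of up to 200 bp the highest share was 17 of 17, at 101 bp. This was the last of several forms of the comparison: one on the middle bases alone and one with a likelihood over windows of each chromosome were tried before it, and the end of chromosome III and the range of shifts were chosen after the windows had been seen. The table does not share its coordinates with WBcel235. Coordinates were not converted, and no position was assigned to a gene, exon, intron or UTR. The planned tests by gene feature, by introns next to circular RNAs and of the 9 gene lists, as well as the planned filters on coverage and editing level, were not run for these reasons. Regions take the place of genes: by the rule fixed before the data were examined for the case without a matching annotation, the 10 C. elegans regions with the most sites are named.

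Listed positions are called sites. Sites at most 1000 bp apart, on either strand, were merged into regions, since neighbouring sites are not independent. Same-strand sites at most 100 bp apart were joined into runs (in the human table, which gives no strand, positions at most 100 bp apart), a definition chosen after the tables were seen. Without a matching genome, the highest listed coordinate stood for the length of each chromosome. Arms were the first and last 33.3% of a chromosome, and a region was placed by its midpoint. The share of regions on arms was tested against 66.7% with a two-sided exact binomial test, with Benjamini-Hochberg adjustment over the 6 chromosomes, and its 95% interval is the exact (Clopper-Pearson) one, which covers counting error of regions only. The median distance to the nearest site was compared with 1000 random placements on the same chromosome and strand. Shares of neighbouring bases have 95% intervals from 1000 bootstrap samples of regions. No background of all adenosines could be had without the genome.

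Within runs whose highest score was at least 5, the mean log2 score of sites with a given neighbouring base was compared with that of the run's other sites, averaged per region, and tested with a two-sided permutation test (100000 sign flips over regions, Benjamini-Hochberg adjustment over 8 tests). This test, with its minimum of 5, was added after the columns of the table were known. The comparison of X with the autosomes, of left with right arms and of regions with at least 100 sites, the counts of runs and the densities per human chromosome were likewise added after the tables were seen. The arm share of the autosomes, the distances between sites and the shares of neighbouring bases were fixed before the data were examined. The base shares were planned against all adenosines of the same gene features. Without a matching genome, G after the site was set against G before it instead. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used. The statistics were tested on simulated data: with 80% of 2515 regions placed on arms, 81.6% were recovered, and a lowering of the log2 score by 1.00 after G was recovered as -1.03 over 468 regions. Some settings of the closing section were revised on the real data. The minimum of known base pairs in the test of self-complementarity was 40 at first, which found 22.5% of 200 simulated inverted repeats; 15, 20, 25 and 30 were then run on simulated and real regions together, and 20 was kept after both had been seen. Shared patterns were first sought over 4 consecutive sites spanning at least 12 bp, without a shuffled control, and then over 8. The longest common span of a run was first read from the steepest fall over 7 bp, which gave 98 bp, and then by the requirement of at least 5 runs at every length from the median span on, which gave 101 bp. Alternatives tried were other arm widths, merging distances and weights, and minimum scores; their effects are given in the closing section.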

Results

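The data comprised 82895 distinct A-to-G sites of C. elegans, deposited for a series of 12 libraries (6 mock and 6 RNase R, stages 1 to 6), and 164872 human positions. The series concerned intron sequences and the formation of circular RNA, and A-to-G differences are the mark that ADAR enzymes leave in double-stranded RNA. In C. elegans, 43179 sites lay on the plus strand and 39716 on the minus strand. The middle base was A on the strand of the site in all 82895. The score had a median of 1 and a mean of 2.33; 64.2% of the sites had a score of 1, and 2.76% reached 10. Depth was unknown, so a site missing from the tables was not evidence of an unedited adenosine. The tables name no library, so no value was assigned to a stage or treatment.

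The first question was where in the genome the sites lay. They formed 2710 regions with a median of 14 sites over a median span of 98 bp. Chromosome I held the most, with 22265 sites in 637 regions. It was followed by chromosome III with 16803 sites in 500 regions, IV with 15621 in 493, II with 12913 in 421 and V with 12065 in 464. Chromosome X held 3228 sites in 195 regions. X thus carried 7.20% of the regions (exact 95% interval 6.25 to 8.23%) on 17.7% of the listed genome length (two-sided exact binomial test, p = 7.71e-57). The autosomes had 30.6 regions per Mb, 2.78 times the density of X, a comparison added after the table was seen. Per Mb, sites ranged from 182 on X to 1478 on chromosome I.

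Within the autosomes, sites were concentrated toward the chromosome ends. Of 2515 autosomal regions, 2117 lay on the arms, which is 84.2% (exact 95% interval 82.7 to 85.6%) against 66.7% of the length (two-sided exact binomial test, p = 1.68e-87). Arms carried 2.66 times as many regions per length as centres. Counted as sites, the arm share was 88.8% (95% interval 86.8 to 90.7%, bootstrap over regions). Among regions with a highest score of at least 2, a limit set after the data were seen, arms carried 4.46 times as many regions per length. All 6 chromosomes departed from the length share in the same direction. The share of regions on arms was 87.6% on I (adjusted p = 3.48e-33, exact binomial test), 85.6% on III, 82.7% on II, 81.9% on IV, 81.7% on V and 76.9% on X (adjusted p = 0.00229, exact binomial test). The 164 autosomal regions with at least 100 sites lay on arms in 148 cases, or 90.2% (exact binomial test, p = 2.88e-12).

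The left and right arms, compared after the table was seen, differed on 4 of the 6 chromosomes. On chromosome I the left arm had 388 regions and the right arm 170, a ratio of 2.28 (adjusted p = 7.85e-20, two-sided exact binomial test over 6 chromosomes). Chromosome IV also had more regions on the left, 262 against 142 (adjusted p = 7.41e-09, exact binomial test). Chromosomes II and III had more on the right, with 207 against 141 (adjusted p = 0.000952, exact binomial test) and 249 against 179 (adjusted p = 0.00125, exact binomial test). The difference between the arms did not pass the test on V (202 left, 177 right, adjusted p = 0.261, exact binomial test) or X (69 left, 81 right, adjusted p = 0.369, exact binomial test). The densest 500 kb interval lay on the left arm of chromosome I, from 1000001 to 1500000, and held 4623 sites in 75 regions, or 5.58% of all sites. The next was on the right arm of chromosome III, from 12500001 to 13000000, with 3681 sites in 64 regions. Regions crowded in this way were counted as independent in the left-right tests, as in those of arms and of X. The p-values of these tests may therefore be too small. The left-right comparison was not repeated at other merging distances.

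**Figure D1:**
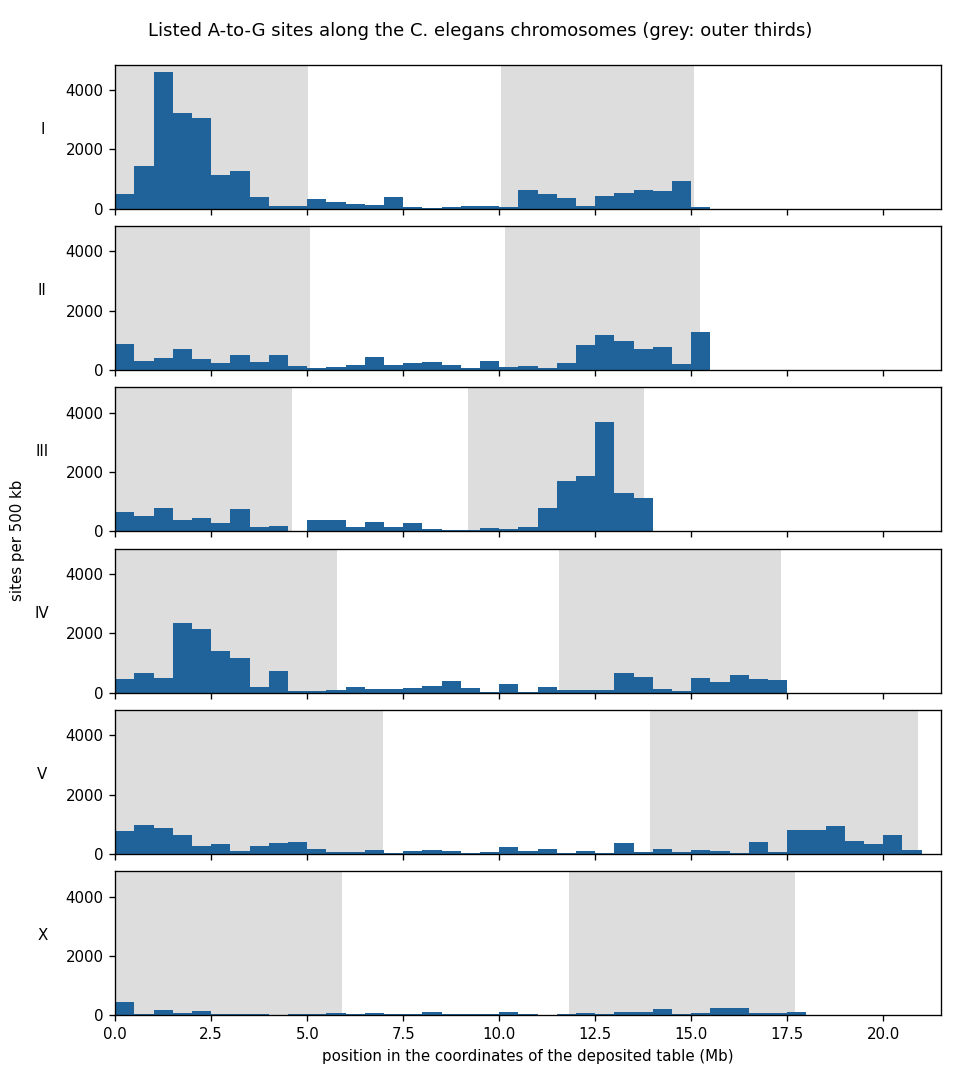
Number of listed A-to-G sites (y axis) per 500 kb of each C. elegans chromosome (x axis, Mb, in the coordinates of the deposited table); grey marks the first and last 33.3% of each chromosome. The tallest bars are on the left arm of chromosome I (4623 sites) and the right arm of chromosome III (3681 sites), and the bars of X are low throughout.

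The 10 regions with the most sites together held 4140 sites, or 4.99% of the table, and 9 of them lay on arms. The largest was at the right end of chromosome III, from 13778793 to 13781346, with 884 sites in 2554 bp, 364 on the plus and 520 on the minus strand. Its highest score was only 12. The second lay on chromosome I, from 10819145 to 10820548, with 431 sites of which 355 were on the plus strand, and its scores were higher, with a median of 5 and a maximum of 132. Regions with at least 90.8% of their sites on the plus strand followed. On chromosome IV, 2359946 to 2367672 held 430 sites, 413 of them on the plus strand. On chromosome III, 12501579 to 12504488 held 405 sites, 388 of them on the plus strand, and 16403696 to 16409911 on chromosome IV held 404, with 367 on the plus strand.

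The remaining 5 of these regions mixed the strands more. They were 1355355 to 1360720 on chromosome I (256 of 359 sites on the plus strand), 1827299 to 1829358 on II (282 plus and 70 minus), 10350689 to 10351570 on IV (141 and 153), 12609059 to 12612215 on III (148 and 144) and 431199 to 435348 on II (190 and 99). The region on IV starting at 10350689 was the only one of the 10 in a chromosome centre; it had 33.3 sites per 100 bp, close to the 34.6 per 100 bp at the right end of chromosome III. In the whole table, 408 regions (15.1%) had sites on both strands, and these held 31020 sites. The highest single score of the table was at position 1155177 of chromosome I on the minus strand. It lay in a region from 1154600 to 1155858 with 190 minus and 22 plus sites, singled out after its value was seen.

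**Figure D2:**
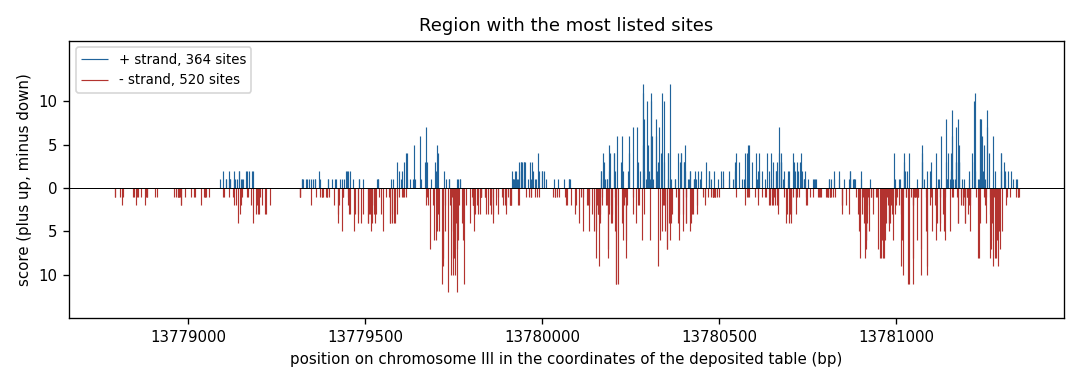
Score of each site (y axis, plus strand upward and minus strand downward) by position (x axis, bp, coordinates of the deposited table) in the region with the most sites, on chromosome III. The region holds 364 plus and 520 minus sites, with stretches that have minus sites alone, and no score is above 12.

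The second question was how closely sites were spaced. The median distance from a site to the nearest other site on its strand was 1 bp, against 696 bp in random placements (range 682 to 709 over 1000 placements). The placement p of 0.000999 is the smallest that these permutations can give. Since the list held no run of fewer than 4 sites, spacing closer than that of single random positions was fixed by the list, and this p says nothing about spacing in the RNA. A directly adjacent site on the same strand was present for 52.9% of sites, and 91.5% had one within 10 bp. Only 5 sites had none within 50 bp. Same-strand runs numbered 4765, with a median of 11 sites over 83 bp. The most frequent run had 6 sites (561 runs), 173 runs had 4 sites, 123 had 5, and none had fewer than 4. Among runs whose scores were all 1, every length from the median span of 66 bp up to 101 bp had at least 5 runs, and 135 runs had one of the last 7 of these lengths against 3 for the next 7 lengths. A rule tried before this one, the steepest fall over 7 bp, placed the fall at 98 bp (219 runs up to it, 37 beyond).

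**Figure D3:**
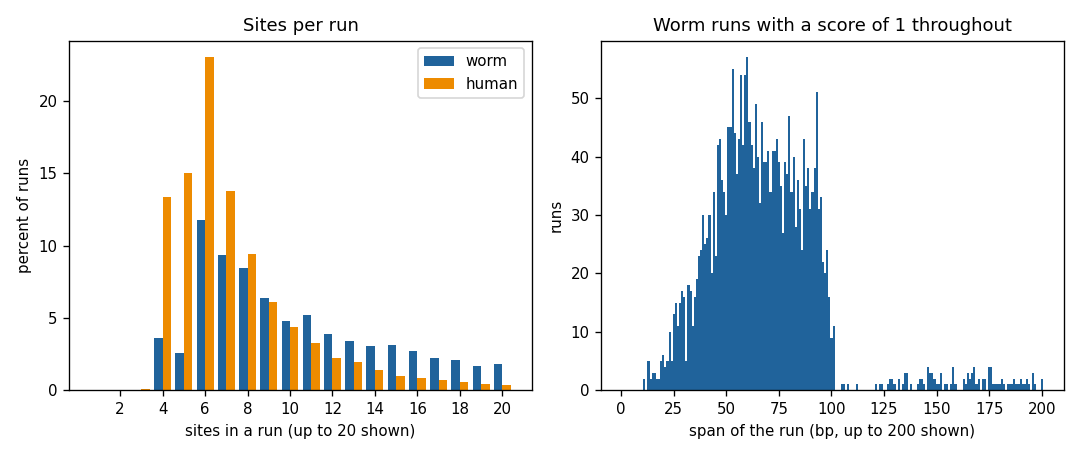
Left: percent of runs (y axis) by number of sites in the run (x axis) in the C. elegans table (same-strand runs) and the human table (runs without regard to strand, a different quantity); each peaks at 6 sites. Right: number of C. elegans runs (y axis) whose scores are all 1 by span (x axis, bp); from the median of 66 bp up to 101 bp every span has at least 5 runs, and runs are sparse beyond.

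The third question was which bases neighbour the sites, since ADAR enzymes are known to disfavour G before the edited adenosine and to favour G after it. On the strand of the site, G preceded 9.60% of sites (95% interval 9.35 to 9.85%, bootstrap over 2710 regions) and followed 17.3% (16.9 to 17.6%). The difference was 7.67 percentage points (95% interval 7.25 to 8.10). It was 7.61 points on the plus strand and 7.72 on the minus strand. Among the 7150 sites with a score of at least 5, its 95% interval was 11.9 to 14.2 points. C showed the opposite, with 15.2% before and 7.56% after the site. A was the most frequent neighbour, with 49.1% before and 52.6% after, and T made up 26.1% before and 22.6% after. These shares were not corrected for the base composition of the regions. Regions that shared a pattern of sites were resampled as independent, so the intervals may be too narrow.

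Within runs, the score of listed sites varied with the neighbouring bases. Adenosines that were not listed had no score and did not enter this comparison. Sites preceded by T scored above the other sites of their run by 0.26 on the log2 scale (SE 0.020, 476 regions, higher in 359). Sites preceded by G scored below the others, with a difference of -0.30 (SE 0.026, 455 regions, lower in 330). After the site, G went with a higher score (0.21, SE 0.021, higher in 327 of 470 regions) and so did A (0.12, SE 0.015, higher in 317 of 476). C after the site went with a lower score (-0.28, SE 0.028, lower in 313 of 440 regions), as did T (-0.17, SE 0.019, lower in 330 of 475). For these 6 bases the adjusted p was 1.33e-05 (permutation test), which rests on the smallest p that 100000 sign flips can give. C before the site differed less (-0.07, adjusted p = 0.00222, permutation test, lower in 273 of 471 regions), and A before the site did not pass the test (-0.02, adjusted p = 0.158, permutation test). Regions were treated as independent, although some shared a pattern of sites with another region, as described under the other observations. The SEs and p-values may therefore be too small, and the test was not repeated without such regions. Full triplets were set against the mean of their run, averaged over all sites rather than per region, and were not tested. Among them, TAG stood highest, at 0.46 above the mean of its run over 1430 sites, and GAC lowest, at -0.60 over 316 sites.

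**Figure D4:**
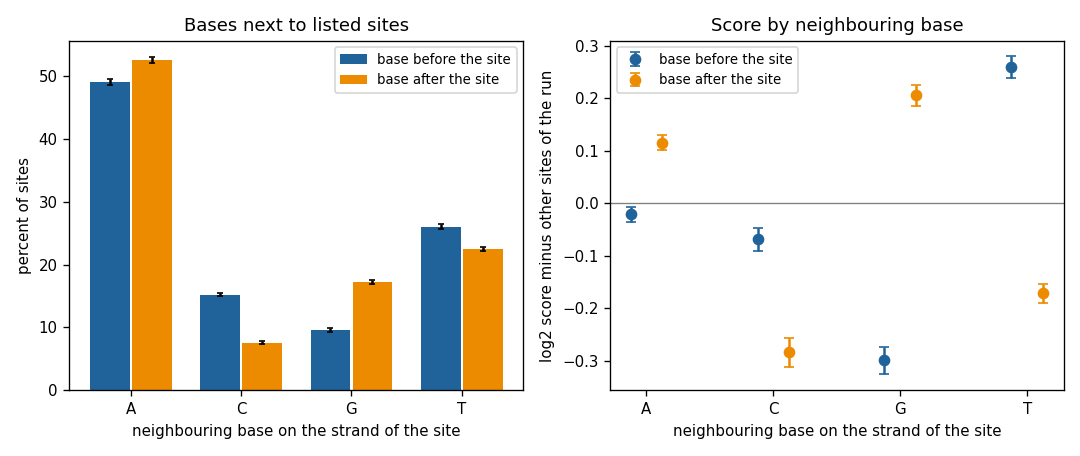
Left: percent of sites (y axis) with each neighbouring base (x axis) before and after the site, with 95% intervals from a bootstrap over regions; G is at 9.60% before and 17.3% after. Right: mean log2 score of sites with each base minus the other sites of the same run (y axis), with bars of 1 SE over regions; T before and G after lie above 0, G before and C after below.

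The human table was examined in sum only. It held 159655 positions on the 22 autosomes, in 18274 regions with a median of 7 positions over 69 bp, against a median of 14 in C. elegans. The median distance to the nearest position was 4 bp, against 5573 bp in random placements (range 5483 to 5654, p = 0.000999 by permutation, the smallest possible with 1000 placements), with the same limit as in C. elegans, since nearly all positions were listed in groups. The human table gives no strand, so its runs joined positions at most 100 bp apart whatever their strand and were not the same quantity as the same-strand runs of C. elegans. The most frequent of these had 6 positions (4813 of 20890), and 26 had fewer than 4. Positions were densest on chromosome 19, with 205 per Mb, which is 4.10 times the median autosome, and on chromosome 17 with 125 per Mb. Chromosome 18 had the lowest density, with 27.9 per Mb. The largest human region held 226 positions, and 15 regions held 100 or more, against 165 in C. elegans.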

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

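The higher density of regions on autosome arms kept its direction and passed the test under all 12 alternatives (for sites in place of regions, by the bootstrap interval), with ratios of arm to centre from 1.83 (without regions that shared a pattern of 4 sites) to 4.46 (regions with a highest score of at least 2), against 2.66. The minimum scores, both sets of regions left out for a shared pattern and the chromosomes left out in turn were chosen after seeing the data; without chromosome I the ratio was 2.44. A minimum score of 2 left 29650 of the 82895 sites and a minimum of 5 left 7150, so most of the table rests on the lowest score. The excess of G after over G before the site was 9.85 points with each region weighted equally, 9.65 with a minimum score of 2, and 11.9 to 14.2 (95% interval) with a minimum of 5. It reversed to -20.0 points among sites with no other site within 50 bp, a set of only 5 sites whose interval ran from -60.0 to 0. The relation of score to neighbouring base kept its call in 15 of 16 alternatives; A before the site passed the test with runs joined at 50 bp (-0.03, adjusted p = 0.0211, permutation test). The share of self-complementary one-strand regions was 19.2% with at least 15 known pairs, 17.9% with 25, 16.2% with 30 and 14.8% with 40, the first setting, against 17.6% with 20; all were above the share of pairings with other regions, and 20 was chosen after seeing the data. The human autosomal regions numbered 20890 when merged at 100 bp and 14878 at 5000 bp, against 18274. No paired analysis was possible because the tables do not separate the mock and RNase R libraries or the stages. Leaving out replicates, filters on coverage and on editing level, random placement within genes, and the alternatives for gene features, circular RNA introns, gene lists and RNase R against mock were not run, since the tables name no samples, coverage, levels or genes. The scored runs, their joining distance and the human merging distances were also chosen after seeing the data. Unknown depth limits every statement on absence.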

Other observations

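All tests in this part were chosen after the patterns had been seen, and the number of known base pairs, the length of shared patterns and the rule for run spans were each changed after an earlier version had been run on these data. No biological explanation from the design was tested, since the tables name no stage or treatment. Several regions outside the 10 with the most sites stood out by score and were picked after their values were seen. The region from 2646466 to 2646867 on chromosome V, on the left arm, had a median score of 12.5, with 97 sites on the plus and 7 on the minus strand. A region from 14346645 to 14346967 on chromosome II had 30 sites, all on the minus strand, with a median score of 6.5. Of the 2026 regions with a run of at least 8 sites, 264 shared a pattern of 8 consecutive sites, with the same triplets and spacing, with another region, and 220 of these shared one with a region on another chromosome. No region did so after the triplets and spacings of each run were shuffled. With the first setting, patterns of 4 sites over at least 12 bp, 1420 of 2710 regions shared one, and so did 295 after shuffling. Of the sharing autosomal regions, 97.7% (of 262) lay on arms, against 84.2% (of 1637) of those that shared none (Fisher's exact test, two-sided, p = 1.06e-11). Sharing regions are by definition not independent of each other, and the number of sites per region was not matched, so this p is a description only. Sequence copies, or the same reads placed at more than one copy, were not told apart.

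Runs of sites had a lower limit in their number of sites, and runs with a score of 1 became much fewer, though not absent, beyond a span of 101 bp. No run of the 4765 had fewer than 4 sites (0 runs); a minimum number of mismatches per read in the authors' calling would give this, but the count is the pattern itself and is no test of that explanation. Runs of 5 sites with a score of 1 numbered 120 and runs of 6 numbered 549. Of runs with a score of 1, the longest of the 290 with 4 or 5 sites spanned 76 bp. Of the 980 with 6 or 7 sites, 19.4% spanned more than this limit, which was taken from the smaller group itself. A hypothesis of 2 read lengths, each with its own minimum, would give this. Runs with more sites can also be longer for that reason alone, and a larger group can hold longer runs. Whether editing only occurs in groups cannot be told apart from a minimum number of mismatches per read. A list made from reads with many mismatches holds few lone sites whatever the RNA held (5 sites had no neighbour within 50 bp).

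The excess of regions on the autosome arms was weighed against 2 technical explanations. Without the regions that shared a site pattern, the arm share was 82.6% (exact 95% interval 81.0 to 84.1%). With the first setting of 4 sites it was 78.6% (76.1 to 80.9%). Copies that matched in such a pattern are therefore not the whole cause of the excess. Copies listed at other sites, or with too few sites for a pattern, stayed in, so repeated copies as such were not excluded. Among regions with a highest score of at least 2 the arm share was 89.9% (88.0 to 91.6%), so the excess does not rest on the regions whose scores were all 1. Inverted repeats that are denser on the arms remain a candidate explanation. The genome was not searched. The share of testable autosomal regions that were self-complementary was 26.6% on arms (144 of 541) and 22.4% in centres (11 of 49). The difference did not pass the test (Fisher's exact test, two-sided, p = 0.613), with only 49 regions in centres, which leaves the density of repeats open.

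The listed triplets give part of the sequence of each region, so regions could be tested for self-complementarity without a genome. Testable regions had at least 30 sites and at least 20 known base pairs at some axis, and 376 of them had at least 95% of sites on one strand. Of these 376, 17.6% (exact 95% interval 13.8 to 21.8%) paired with themselves above a limit that 0.600% of pairings with other regions passed. RNA that folds back on itself as an inverted repeat would give this. The limit came from pairings between different regions, so it does not account for other repetition of sequence within a region. In simulated regions the test found 96.5% of 200 inverted repeats and none of 200 others. The simulated repeats had long, nearly complementary arms, and the others were random bases without repeats of any kind. These simulated shares therefore need not hold for the real regions. Among the 231 testable regions with more than 5% of sites on the smaller strand, 93 (40.3%) passed the limit, against 1.67% of pairings with other regions of like strand mix, and over all 607 testable regions 26.2% passed it. In 100 self-complementary regions with at least 4 sites on each strand, a median of 54.8% of the smaller strand's sites lay opposite a listed site of the other strand, but such pairs are themselves matches that helped to choose the axis and the region, so whether reads of one transcript were placed on both arms of a repeat cannot be told apart from editing of both strands. Transcription of both strands also stays open. Of the testable regions with more than 5% of sites on the smaller strand, 138 stayed under the limit. This does not show that they lack an axis, since 13 of them matched at 80% or more of their known pairs.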
